A study of Escherichia coli BW25113 with 4 samples.

How the data were processed

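RNA was sequenced from Escherichia coli K-12 BW25113 and from a derivative of it in which cyaA, the gene of adenylate cyclase, had been knocked out. Per the labels, cells were harvested from LB, a rich medium, at 37 °C while growing exponentially, RNA was extracted with a column kit, rRNA was depleted and libraries were made and sequenced by a commercial provider. There were 4 libraries, 2 per genotype, and each library's genotype was taken from its label. The labels do not say that the replicates of a genotype came from separate cultures, so the p-values given here measure only the spread between these samples, which may be technical.

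The authors deposited one table per library of raw counts of reads per gene, with the position, strand and length of each gene, per the file headers. Trimmomatic 0.36, Bowtie2 2.2.6, featureCounts and Subread 1.5.2 are named in the submitters' processing notes. Their roles and settings, including the use of strand and the handling of reads that map to several places, are not given in the sources used here. Reads of a gene and of RNA from its opposite strand therefore cannot be told apart. Near-identical copies such as gadA and gadB, and the multicopy rRNA and tRNA genes, have uncertain counts. The files list 4419 features on the chromosome of K-12 MG1655, and 4414 of their identifiers matched the locus tags of the reference gene table of assembly ASM584v2, from which the symbols were taken. Start and end were the same in both for 4371 features, and positions are given as the count files give them. The 5 identifiers with no symbol held at most 0.00341% of the counts of a library and stayed in the tests.

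The total counts were 11473139 and 12942710 in wild type and 10961872 and 11530755 in the knockout, so that 3 counts correspond to 0.232 to 0.274 counts per 1000000 (CPM). Between the replicates of a genotype, counts of single genes differed by more than sampling noise, with a chi-square per degree of freedom of 31.2 over 4041 genes in wild type and 2.09 over 4209 genes in the knockout, and each library was kept as 1 replicate. The Spearman correlation across genes was 0.997 between the wild-type libraries and 0.998 between the knockout libraries, and lay between 0.774 and 0.783 for libraries of different genotype, where genes are not independent replicates.

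Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by edgeR's expression filter with a minimum count of 10, which left 4212 genes and removed 207. Library sizes were scaled by the trimmed mean of M-values (TMM), with factors of 0.840 and 0.845 in wild type and 1.20 and 1.17 in the knockout. The quasi-likelihood F-test with robust dispersion was applied to the genotype alone, and p-values were adjusted by the Benjamini-Hochberg method over all tested genes. An adjusted p under 0.05 is called past the threshold. The common biological coefficient of variation was 6.53%, with 2 residual and a median of 5.46 prior degrees of freedom. The fit gives both genotypes the same dispersion for a gene, so p-values and standard errors assume equal spread. The wild-type replicates differed more than the knockout replicates, and no alternative allowed for this. CPM are normalised with the TMM factors unless stated otherwise. Log2 fold changes are knockout over wild type, given with the standard error (SE) derived from the F statistic, and standard deviations (SD) are over the 2 libraries of a genotype.

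Gene lists were tested with camera in limma 3.58.1, two-sided, at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 35 lists that had at least 3 tested members. The camera test asks whether the members of a list shifted relative to all other genes. It was repeated with the correlation estimated from the data, which leaves the test 2 residual degrees of freedom. Of 921 entries in 36 lists, 912 matched a gene of the files, 4 of them through a recorded synonym, 8 did not match and 1 was a second name of a gene already in its list. The last of the lists, the genes deleted in the parent strain, was only described.

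The groups, the lists, the tests, the first 10 alternatives and the rule for naming genes were chosen before the data were examined. The rule always names cyaA, cpdA, crp, prfA, prfB, prfC, rmf, fis, spf, tnaA and the genes next to cyaA. It adds the 10 largest increases and the 10 largest decreases past the threshold among genes with a mean count of at least 50 in the higher genotype and with both knockout libraries on the same side of both wild-type libraries, rRNA genes left out. From each list it takes up to 3 members past the threshold in the direction of most of its members and up to 1 in the other direction, with the same count minimum. Genes named outside the rule are given as such.

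The 10 alternatives were the size factors of DESeq2 in edgeR, no filter on low counts, the Wald test of DESeq2 1.42.0, limma-voom, a block for the replicate number, rRNA and tRNA genes left out, and each of the 4 libraries left out in turn. The estimated correlation applied to the lists alone. Scaling by total count and by upper quartile, 2 further alternatives, were chosen after seeing the data. The correlation across genes between the deviations of number 1 in both genotypes was 0.0102. With 2 libraries per genotype there is only 1 such value, so it cannot show whether libraries of the same number were handled together. The fits were tested on simulated counts for 4212 genes with the library sizes of these libraries and 200 changed genes. Each gene had its mean over both genotypes and 1 spread for both. The changes were balanced in direction and spared most genes. Scaling when most genes differ and unequal spread between the genotypes were therefore not tested. With 50 genes at each size of change, edgeR recovered 84% of those changed 1.5-fold, 92% at 2-fold, 98% at 4-fold and 100% at 8-fold, and called 18 unchanged genes. In the same simulation DESeq2 recovered 82%, 84%, 98% and 98% with 12 unchanged genes called, and limma-voom 84%, 92%, 98% and 98% with 18. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.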

Results

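The transcriptome of E. coli BW25113 growing in LB was compared with that of its cyaA knockout, with 2 libraries per genotype. Adenylate cyclase, the product of cyaA, makes cyclic AMP (cAMP), which acts through the cAMP receptor protein (CRP), a regulator of many genes for the use of alternative carbon sources. The series is about how metabolism, through cAMP, regulates the accuracy of translation, and the comparison asks which transcripts differ between the parent and the strain with a knocked-out adenylate cyclase gene. The level of cAMP was not analysed here. Libraries held 10961872 to 12942710 counts. The 10 most abundant genes took 26.5% and 27.3% of the counts in wild type and 24.5% and 24.9% in the knockout. The shares of rRNA genes were 3.64% and 4.54% in wild type and 4.29% and 4.64% in the knockout, and ssrA, the transfer-messenger RNA, took 6.70% and 7.17% of the counts in wild type and 11.2% and 11.6% in the knockout.

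The gene cyaA, knocked out per the labels, was lower in both knockout libraries. The count of cyaA (b3806, positions 3991153 to 3993699 on the plus strand of the K-12 MG1655 chromosome) was 4593 and 5325 in wild type and 1300 and 1344 in the knockout, or 482 ± 7.25 and 99.1 ± 0.729 normalised CPM (SD, n = 2 each). It fell with a log2 fold change of -2.28 ± 0.05 (SE; adjusted p = 2.6e-09, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The transcript was therefore lower but not absent, and a single count per gene does not show which part of the locus the remaining reads came from. Of the list of genes for cAMP and CRP, crp itself fell (-1.72 ± 0.05), as did cpdA, the gene of the phosphodiesterase that degrades cAMP (-1.77 ± 0.05), while fis, a nucleoid protein abundant in fast growth, rose (1.71 ± 0.09). In that list 2 of 5 members rose and 3 fell (camera adjusted p = 0.25).

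Around cyaA, the list of neighbours moved downward, with 8 of 11 members lower, 1 higher and 2 not past the threshold (median -1.16; camera adjusted p = 0.016, and adjusted p = 0.353 with an estimated correlation). The heme synthesis genes hemC (-1.50) and hemD (-1.28) on one side fell, as did hemX (-1.89) and hemY (-2.01) next to them. On the other side lptM (-1.46), yigA (-0.89), dapF (-1.16) and xerC (-0.57) were lower, while cyaY (-0.04) and yigB (-0.15) did not pass the threshold and uvrD, a DNA helicase gene, rose (0.44). The call for this list was lost with DESeq2 (adjusted p = 0.0751, range 0.00547 to 0.0751 over the 12 alternatives). With total-count scaling xerC no longer passed (-0.08), and cyaY (0.46) and yigB (0.34) passed upward.

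**Figure D1:**
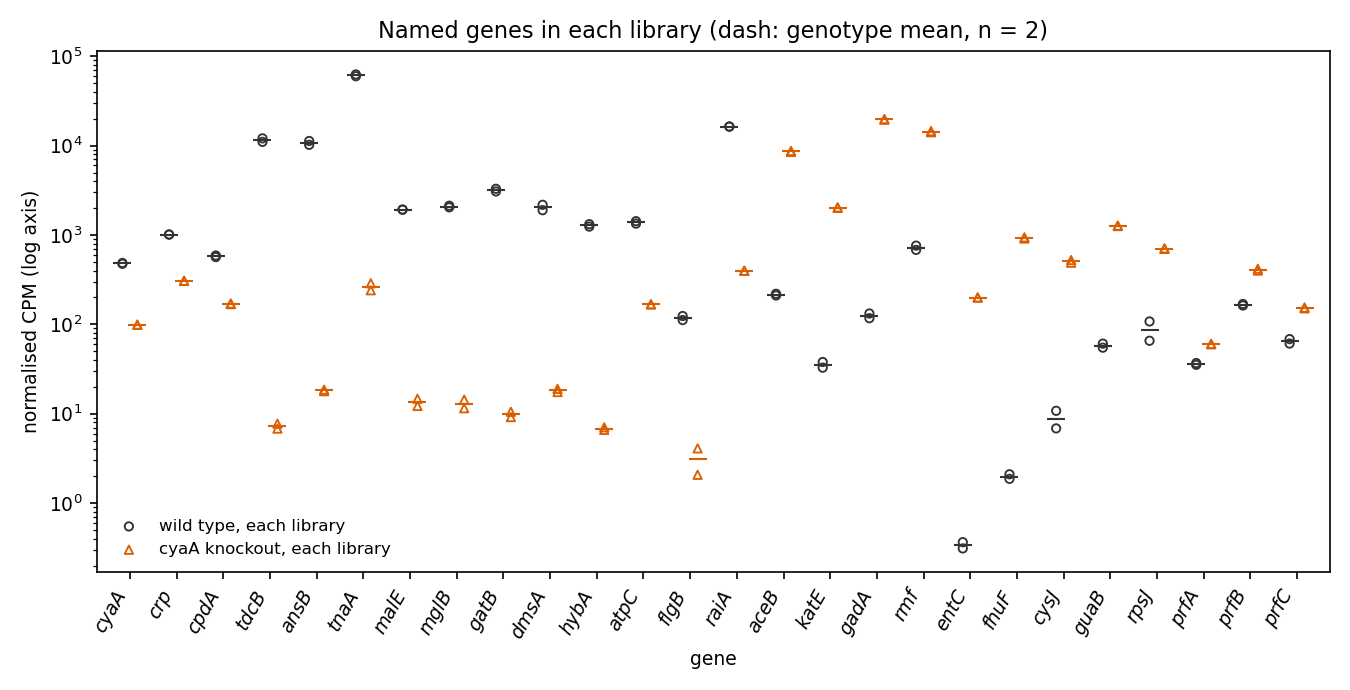
Normalised CPM of 26 named genes on a log axis in each library. Open circles are the wild-type libraries, open triangles the cyaA knockout libraries, and dashes the genotype means (n = 2). The values of cyaA lie at 482 CPM in wild type and 99.1 CPM in the knockout on average, and those of tdcB at 11542 and 7.28 CPM.

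Most of the transcriptome differed between the genotypes. Of 4212 tested genes 1753 were higher and 1749 lower in the knockout, and 710 did not pass the threshold, so that 83.1% were called. Changes of at least 2-fold past the threshold numbered 980 upward and 1042 downward, and 98 genes rose and 176 fell at least 16-fold. The upward calls made up 50.1% of all calls. With the library totals alone as scaling, all genes shifted upward by a median of 0.49 on the log2 scale, 2363 genes were called higher and 1222 lower, and the upward share became 65.9%. Upper-quartile scaling gave a shift of 0.22, with 2030 higher and 1525 lower. Directions below are therefore relative to the bulk of the genes, as TMM scaling sets it, and small changes depend on it.

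**Figure D2:**
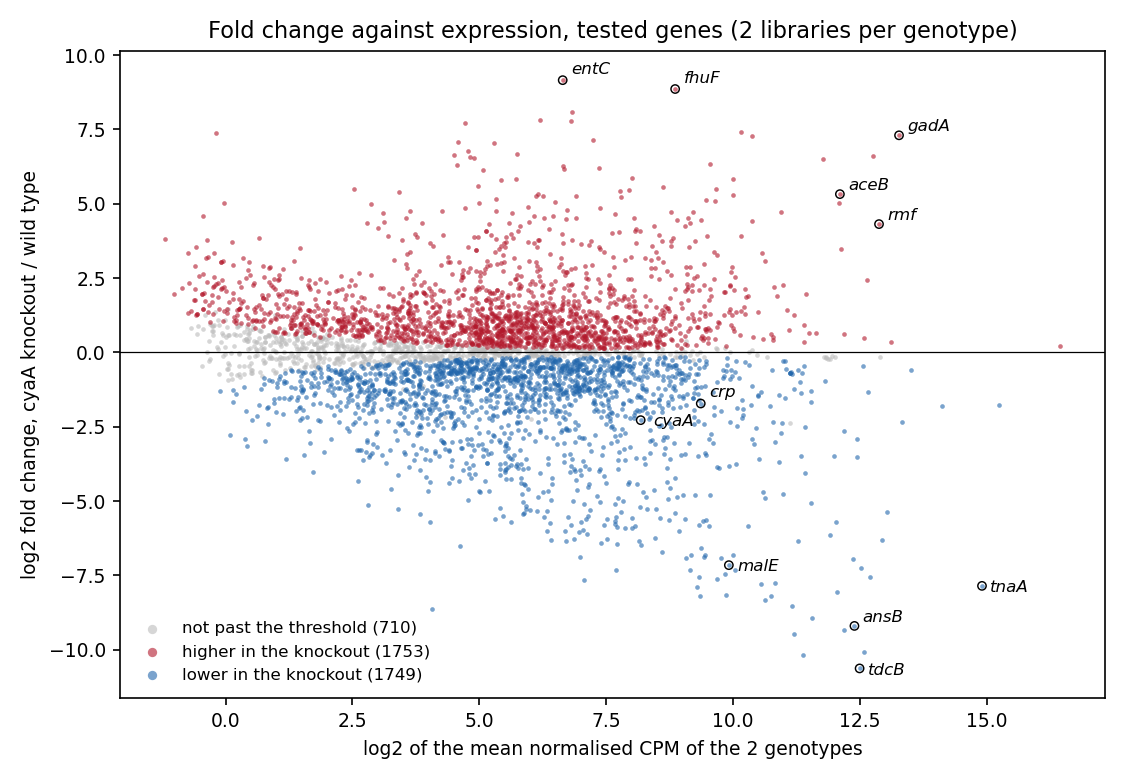
Log2 fold change, knockout over wild type, against the log2 of the mean normalised CPM for the 4212 tested genes. Red points are the 1753 genes higher in the knockout, blue points the 1749 lower and grey points the 710 not past the threshold, and circles mark 11 named genes, among them entC at 9.15 and tdcB at -10.63.

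Most of the 10 largest decreases were in genes for the breakdown and uptake of amino acids. In the tdc operon for the anaerobic breakdown of threonine and serine, tdcB, the gene of threonine dehydratase (b3117, positions 3265039 to 3266028), went from 11542 ± 739 to 7.28 ± 0.648 CPM (SD, n = 2 each), a log2 fold change of -10.63 ± 0.13 (SE; adjusted p = 4.2e-10, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Its operon partners tdcD (-10.19), tdcC (-10.07), tdcA (-9.48) and tdcE (-9.33) fell by similar amounts. The asparaginase gene ansB (-9.20) fell, and so did tnaA (-7.85), for tryptophanase, and tnaB (-8.93), for a tryptophan permease. The gene tnaA (b3708) was abundant in wild type, at 61200 ± 1988 CPM against 265 ± 33.4 in the knockout. The remaining large decreases by the naming rule were ompW, an outer membrane protein gene (-8.54), gatB of galactitol uptake (-8.33) and ykgR. The small gene ykgR had 352 and 338 counts in wild type and 2 and 0 in the knockout, which is 0.224% of the wild-type level after scaling (95% exact binomial interval 0.0270% to 0.811%, counting error only). Its fitted log2 fold change of -8.62 became -7.70 without knockout replicate 2. Without knockout replicate 1 it became -11.58, where 0 knockout counts remain and the fitted value is no bound.

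The 10 largest increases included genes of iron uptake, acid resistance and several of unknown function. The gene entC (b0593) of enterobactin synthesis had 3 and 4 counts in wild type and 2627 and 2702 in the knockout, a fitted log2 fold change of 9.15 ± 0.12 that rests on very few wild-type counts. The ferric reductase gene fhuF (b4367) went from 1.98 ± 0.166 to 928 ± 19.6 CPM (SD, n = 2 each; 8.86 ± 0.09, adjusted p = 4.2e-10, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Also in this set were entE (8.08) and fes (7.83) of the enterobactin system, nrdI (7.70, with 0 and 5 counts in wild type, 6.81 without wild-type replicate 1, and 12.32 without replicate 2, where 0 wild-type counts remain and the fitted value is no bound) of the manganese-dependent ribonucleotide reductase, and the glutamate decarboxylase gene gadA (7.30). The genes yjcB (7.76), ybgS (7.42), ymdF (7.27) and yciG (7.15) completed it. In wild type entE, fes and yjcB lay at 0.820, 0.631 and 1.02 CPM on average, so their fold changes also rest on few wild-type counts.

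Across the gene lists fixed beforehand, 24 of 35 shifted relative to all other genes, 9 upward and 15 downward. None of these calls held with a correlation between genes estimated from the data by camera, where their adjusted p ran from 0.258 to 0.665. Over all 35 lists it ran from 0.258 to 0.991, and 5 had an unadjusted p under 0.05. That version of the test has only 2 residual degrees of freedom. Counts of members adjusted over the list alone were the same as those over all genes in 31 lists, and the other 4 are given where they occur.

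Genes for the uptake and use of several sugars were lower as groups. Maltose genes fell in 10 of 11 cases, led by the binding protein gene malE (-7.16 ± 0.11) and the maltoporin gene lamB (-6.57 ± 0.08), while malZ rose (0.76; list median -2.70, camera adjusted p = 1.7e-06, and adjusted p = 0.303 with an estimated correlation). All 6 ribose genes fell, with rbsD at -5.66 (median -4.44; 8.6e-10 by camera, and adjusted p = 0.258 with an estimated correlation). Of 9 galactose genes 8 fell, among them mglB of the methyl-galactoside transporter (-7.33), and galP, a galactose permease gene, rose (2.66; camera adjusted p = 7.5e-04, and adjusted p = 0.298 with an estimated correlation). In the list of the phosphotransferase system, which holds its general components and the glucose transporter as well as those of other sugars, 26 of 33 were lower, 6 higher and 1 not past the threshold, with gatA at -8.20 (camera adjusted p = 5.7e-10, and adjusted p = 0.298 with an estimated correlation). Of 24 genes for pentoses and other sugars 19 fell, including fucA (-5.51), and 1 rose, or 2 when adjusted over the list alone (camera adjusted p = 2.4e-05, and adjusted p = 0.297 with an estimated correlation). The glycerol list did not shift (3 of 11 higher, 6 lower, with glpT at -2.72 and glpE at 1.65; camera adjusted p = 0.95), and there the median (-0.20) and mean (-0.10) were negative, the test pointed upward and the median became 0.29 with total-count scaling.

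Of 37 genes of amino acid catabolism 24 fell, 12 rose and 1 did not pass, or 24 and 13 when adjusted over the list alone (median -1.99; camera adjusted p = 4.2e-06, and adjusted p = 0.298 with an estimated correlation). The members that rose included astC of arginine breakdown (3.78). Nucleoside catabolism had 6 of 11 genes lower, such as the nucleoside channel gene tsx (-3.92), and 4 higher, such as deoB (2.08), and did not pass as a list (camera adjusted p = 0.075). Fatty acid oxidation was mixed, with 5 of 12 genes higher, fadE among them (1.72), 4 lower, fadH among them (-2.24), and 3 not past the threshold (camera adjusted p = 0.75). Its median was positive (0.12), as was its mean, while the test pointed downward.

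Genes of the TCA cycle, the ATP synthase and respiration were mostly lower in the knockout, while the glyoxylate shunt gene aceB rose. Of 20 genes of the TCA cycle and the shunt 15 fell, led by the anaerobic fumarase gene fumB (-7.63 ± 0.09), with sucB at -4.05 and sdhB at -3.89, and 5 rose (camera adjusted p = 0.0048, and adjusted p = 0.516 with an estimated correlation). The malate synthase gene aceB of the shunt was the member with the largest rise, from 215 ± 6.66 to 8609 ± 156 CPM (SD, n = 2 each; 5.32 ± 0.09). All 9 ATP synthase genes fell, with atpC at -3.05 (median -2.37; camera adjusted p = 2.8e-05, and adjusted p = 0.391 with an estimated correlation), and so did all 22 respiratory chain genes, with cydA of the cytochrome bd oxidase at -5.08 (median -1.68; 2.8e-06 by camera, and adjusted p = 0.298 with an estimated correlation). With total-count scaling 1 of them, cyoA, named after its values were seen, turned from -0.27 to 0.22. Anaerobic respiration and fermentation had 38 of 44 genes lower, including the hydrogenase gene hybA (-7.55) and the dimethyl sulfoxide reductase gene dmsA (-6.80), 2 higher, including ldhA (0.81), and 4 not past the threshold (camera adjusted p = 5.0e-13, and adjusted p = 0.391 with an estimated correlation).

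Gluconeogenesis genes fell in 6 of 7 cases, with pck at -6.35 (camera adjusted p = 0.0048, and adjusted p = 0.298 with an estimated correlation). Of 11 genes for acetate and C4-dicarboxylates 8 fell and 2 rose, with dcuB at -7.88 and poxB, a pyruvate oxidase gene, at 2.86 (camera adjusted p = 0.0037, and adjusted p = 0.298 with an estimated correlation). Glycolysis had 9 of 13 genes higher, among them pykF (2.26), and 2 lower, among them pykA (-1.15), the genes of both pyruvate kinases (median 0.43; camera adjusted p = 0.14). The glycolysis list passed when either wild-type library was left out (0.0468 without replicate 1, 0.0442 without replicate 2, range 0.0442 to 0.168 over the 12 alternatives).

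Many genes of the translation apparatus were higher, those of ribosomal proteins above all. Of 54 ribosomal protein genes 48 rose, 3 fell and 3 did not pass (median 1.47; camera adjusted p = 1.0e-05, and adjusted p = 0.613 with an estimated correlation). The largest rises in the list were rpsJ (3.03 ± 0.29) and rplC (2.95 ± 0.32), and rpmF fell (-0.88). The wild-type libraries lay far apart for both, with rpsJ at 86.7 ± 29.9 CPM in wild type and 704 ± 8.16 in the knockout. For rplC the values were 159 ± 57.6 and 1228 ± 28.0 CPM (SD, n = 2 each). The release factor genes rose, with prfA, for RF1, at 0.74 ± 0.07, prfB, for RF2, at 1.30 ± 0.05, and prfC, for RF3, at 1.24 ± 0.07. In normalised CPM prfB went from 166 ± 4.59 to 409 ± 13.3 and prfA from 36.1 ± 1.17 to 60.2 ± 0.510 (SD, n = 2 each). The list of release and ribosome rescue factors had 9 of 11 genes higher, with arfA at 2.09, and 1 lower, smpB, the partner of transfer-messenger RNA (-1.14). It missed the threshold (camera adjusted p = 0.12) and passed in 4 alternatives, limma-voom (0.0284), no filter (0.0366), total-count scaling (0.0350) and upper-quartile scaling (0.0335), with a range of 0.0284 to 0.156 over all 12.

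Of 15 initiation and elongation factor genes 7 rose, among them bipA (2.30), 3 fell, among them selA of selenocysteine incorporation (-2.11), and 5 did not pass (median 0.13; camera adjusted p = 0.54). Aminoacyl-tRNA synthetase genes rose in 17 of 24 cases and fell in 4, with argS at 1.69 and serS at -1.61 (camera adjusted p = 0.083, range 0.00500 to 0.140 over the 12 alternatives). That list passed in 6 of them, which were limma-voom, no filter, both added scalings, and leaving out wild-type replicate 1 (0.0468) or 2 (0.0402). Of 71 genes for the modification of tRNA and rRNA 48 rose, with miaB at 2.17, and 12 fell, with rlmD at -1.04 (median 0.53; camera adjusted p = 0.0046, and adjusted p = 0.471 with an estimated correlation).

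Among 83 tRNA genes, 47 were higher, 10 lower and 26 not past the threshold, with asnT at -2.50 ± 0.13 and pheU at 2.23 ± 0.30 (median 0.52; camera adjusted p = 0.044, and adjusted p = 0.637 with an estimated correlation). The call was lost with DESeq2 (0.0725), without wild-type replicate 1 (0.0706) and without knockout replicate 2 (0.0724), over a range of 0.00412 to 0.0725 in 11 alternatives. The level of pheU was low, at 1.84 ± 1.14 CPM in wild type and 8.92 ± 0.386 in the knockout (SD, n = 2 each), and its log2 fold change became 3.11 without wild-type replicate 2. The share of counts in tRNA genes was 0.269% and 0.277% in wild type and 0.545% and 0.555% in the knockout. Of 22 rRNA genes 12 were lower and none higher, or 10 lower when adjusted over the list alone (median -0.69; camera adjusted p = 0.69, range 0.0244 to 0.981 over 11 alternatives, limma-voom alone passing). The 3 rRNA species differed, since all 7 of the 16S genes and 5 of the 8 5S genes were lower and none of the 7 23S genes passed (medians -0.69, -1.24 and -0.17). With total-count scaling all 7 of the 23S genes were higher (median 0.32), no 16S gene passed (median -0.19) and 1 of the 5S genes was lower (median -0.75). With upper-quartile scaling 7 of the 16S genes (median -0.47) and 4 of the 5S genes (median -1.02) were lower and no 23S gene passed (median 0.05). The ratio of 23S to 16S counts, which scaling leaves as it is, was 1.46 and 1.35 in wild type and 2.01 and 1.95 in the knockout, a gap of 0.489 against a largest difference of 0.118 within a genotype. For rrfA, a 5S gene, the call (-1.86 ± 0.46) was lost without knockout replicate 1 or 2 (-1.54 and -2.28), and the value became -1.22 without wild-type replicate 2. These RNAs had been depleted or are poorly kept by library preparation, and the counts of identical copies are uncertain.

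Acid resistance genes and many stationary-phase genes were higher. All 15 acid resistance genes rose, with gadA going from 125 ± 10.7 to 19667 ± 271 CPM (SD, n = 2 each), gadB at 6.60 and the antiporter gene gadC at 6.50 (median 3.75; camera adjusted p = 2.2e-15, and adjusted p = 0.258 with an estimated correlation). The near-identical gadA and gadB may share reads. In the list of ribosome hibernation and stationary phase 14 of 22 genes rose and 6 fell (camera adjusted p = 0.011, and adjusted p = 0.516 with an estimated correlation). Its members that rose included the catalase gene katE (5.84), osmY (4.73) and rmf, for ribosome modulation factor, which pairs ribosomes into inactive dimers (4.31 ± 0.09, from 721 ± 55.9 to 14336 ± 305 CPM). In contrast raiA, for another protein that silences idle ribosomes, fell from 16343 ± 22.7 to 398 ± 0.289 CPM (-5.36 ± 0.09). This list missed the threshold with total-count scaling (0.0551, range 0.00203 to 0.0551 over the 12 alternatives). Heat shock genes rose in 17 of 21 cases, with hslO, a chaperone gene, at 1.86, and fell in 3, with clpA at -1.23 (median 0.66; camera adjusted p = 0.028, and adjusted p = 0.665 with an estimated correlation), a call lost with DESeq2 (0.0663, range 0.00372 to 0.0663).

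Motility genes were lower, with 42 of 52 genes of flagella and chemotaxis down, 1 up and 9 not past the threshold. The rod gene flgB was at -5.26 ± 0.19 and aer, the aerotaxis receptor gene, at 0.64 (median -1.94; camera adjusted p = 1.1e-06, and adjusted p = 0.353 with an estimated correlation). Of 5 curli genes 2 rose, with csgD at 1.13, or 1 when adjusted over the list alone, and 3 did not pass (camera adjusted p = 0.71). The porin list also holds genes that are not for porins, such as those of lipoproteins, a protease and a regulator. Of its 13 tested genes 9 fell, with ompF at -6.13, and 3 rose, with ompX at 2.18 (camera adjusted p = 0.032, and adjusted p = 0.353 with an estimated correlation). The porin call was lost when either knockout library was left out (0.0613 without replicate 1, 0.0608 without replicate 2, range 4.3e-04 to 0.0613).

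Iron acquisition was the list with the highest median. Of its 45 genes 42 rose and 3 fell (median 4.31; camera adjusted p = 1.0e-28, and adjusted p = 0.258 with an estimated correlation), with entC and fhuF at the top and feoC, of ferrous iron uptake, at -0.71, a value that did not pass with total-count scaling (-0.21). Biosynthetic genes rose on balance. Amino acid biosynthesis had 56 of 94 genes higher, with the sulfite reductase gene cysJ at 5.86, 21 lower, with asnA at -3.60, and 17 not past the threshold (median 0.52; camera adjusted p = 0.0016, and adjusted p = 0.297 with an estimated correlation). Nucleotide biosynthesis had 21 of 29 genes higher, with guaB of guanine nucleotide synthesis at 4.45, and 6 lower, with pyrI at -2.45 (median 1.24; camera adjusted p = 0.0012, and adjusted p = 0.353 with an estimated correlation).

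Small RNA genes moved both ways, with 9 of 21 higher, 11 lower and 1 not past the threshold (median -0.54, mean 0.07; camera adjusted p = 0.98, the test pointing downward). The iron-responsive ryhB rose (5.39 ± 0.22, from 0.482 ± 0.0944 to 20.8 ± 1.25 CPM, SD, n = 2 each), a value that rests on few wild-type counts. In contrast fnrS, an RNA made without oxygen, fell (-5.98 ± 0.12). The gene cyaR, known to be activated by CRP, fell (-2.21 ± 0.19), and spf, for Spot 42 RNA, which is known to be repressed by CRP with cAMP, also fell (-0.96 ± 0.13, from 16.4 ± 0.458 to 8.43 ± 0.871 CPM, SD, n = 2 each). Short RNAs are kept unevenly by library preparation. Of the genes deleted in the parent strain, araB, araA and rhaA had 0 counts in all 4 libraries, and rhaB had 2 counts in 1 wild-type library and 0 elsewhere. The gene lacZ had 11 and 14 counts in wild type and 47 and 48 in the knockout, araD 4 and 4 against 12 and 17, and rhaD 3 and 3 against 11 and 6.

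**Figure D3:**
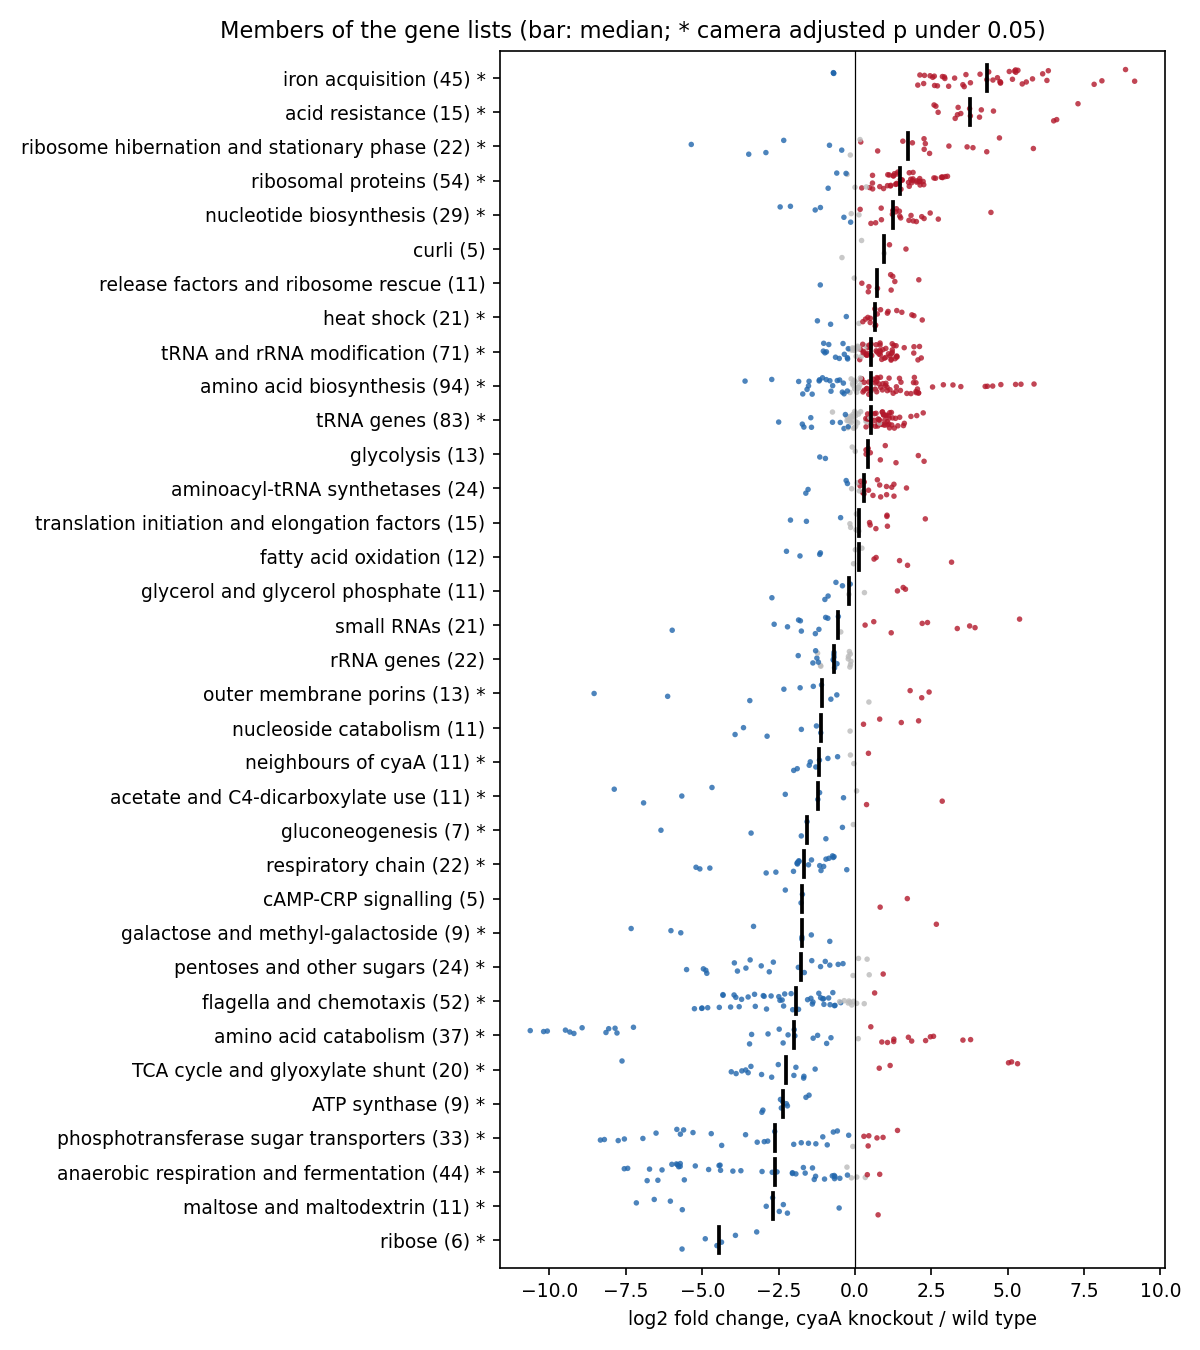
Log2 fold change, knockout over wild type, of the tested members of 35 gene lists, ordered by median, with the number of tested members in brackets. Points are genes, red where higher and blue where lower past the threshold and grey where not, black bars are list medians, and an asterisk marks a camera adjusted p under 0.05 at the preset correlation. Medians run from -4.44 for ribose to 4.31 for iron acquisition, and that of the rRNA genes becomes -0.20 and that of the glycerol genes 0.29 with total-count scaling.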

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

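Scaling by total count and by upper quartile were the tests chosen only after the results were seen, and the others were planned. The counts of genes higher and lower stayed within 1.5 times of 1753 and 1749 under all 12 alternatives, from 1538 to 2363 upward and 1222 to 1771 downward, and the fold change of cyaA stayed past the threshold in each. Of the genes called, 1483 higher and 1562 lower kept their call under the 10 alternatives chosen beforehand, and 1483 and 1218 also under the 2 added ones. The number of lists that shifted stayed between 21 and 27 except with an estimated correlation, where it was 0, by a test with 2 residual degrees of freedom, and 5 lists had an unadjusted p under 0.05. Of the 121 genes named and tested, 113 kept their direction and side of the threshold in all 12 alternatives (11 for tRNA and rRNA genes), and of 35 lists 26 did so, the estimated correlation aside. The log2 fold change of cyaY became 0.4553 with total-count and 0.1832 with upper-quartile scaling, and with total-count scaling that of yigB became 0.3446, that of cyoA 0.2241 and that of nikR 0.1116, the last not past the threshold. These scalings move all genes by one common amount, which was upward here. Leaving out a library leaves its genotype with 1, assumed to vary like the other genotype. Depth limits genes near the floor in 1 genotype, such as entC with 3 and 4 counts and nrdI with 0 and 5 in wild type, whose fold changes rest on few counts.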

Other observations

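All tests in this part were chosen only after the results were seen, and the gene families in the first paragraphs were grouped by the first 3 letters of their names. The genes named there lie outside the naming rule and were chosen after their values were seen.

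Several gene families that lay mostly outside the lists shifted at the preset correlation, and none of these calls held with an estimated one (adjusted p = 0.857 for each). The nikABCDE and nikR genes of nickel uptake all fell (6 of 6, median -3.98, camera adjusted p = 0.019, and adjusted p = 0.857 with an estimated correlation), with nikA at -5.80, although nikR (-0.38) was at 0.11 with total-count scaling. The 7 hyp genes, 6 of them for hydrogenase assembly or maturation, also fell, with hypB at -5.25 (median -3.55, camera adjusted p = 2.8e-05, and adjusted p = 0.857 with an estimated correlation). Universal stress protein genes, 3 of them also in the lists, fell in 6 of 7 cases (median -2.55, camera adjusted p = 0.0050, and adjusted p = 0.857 with an estimated correlation), with uspF at -4.58, while uspB rose (1.57). All 4 xdh genes of xanthine dehydrogenase and its kin fell (median -2.25, camera adjusted p = 0.039, and adjusted p = 0.857 with an estimated correlation), with xdhA at -3.68.

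In the other direction, all 5 isc genes of iron-sulfur cluster assembly rose (median 1.96, camera adjusted p = 0.0087), with iscR at 3.12, and all 4 bet genes of choline uptake and glycine betaine synthesis (median 2.33, camera adjusted p = 0.017), with betB at 2.79, both at adjusted p = 0.857 with an estimated correlation. All 5 ugp genes of glycerol phosphate uptake rose (median 3.31, camera adjusted p = 0.026), with ugpB at 3.31, as did all 4 pao genes of an aldehyde oxidase (median 3.40, camera adjusted p = 0.032), with paoC at 3.49, again both at adjusted p = 0.857 with an estimated correlation. Of 5 osm genes 4 rose (median 3.37, camera adjusted p = 0.0096), with osmC at 3.37, and of 5 app genes 4 rose (median 4.09, camera adjusted p = 5.2e-05), with appC, of a second cytochrome bd oxidase, at 4.71, and each had an adjusted p = 0.857 with an estimated correlation. All 11 dna genes of replication and of the DnaK chaperone system rose by smaller amounts (median 0.87, camera adjusted p = 0.046, and adjusted p = 0.857 with an estimated correlation), with dnaA at 1.34. Camera tested 245 families of at least 4 genes and called 44, of which 11 lay mostly outside the lists. With an estimated correlation it called 0, the lowest adjusted p being 0.857, and 8 families had an unadjusted p under 0.05.

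The first pattern is the cyaA count left in the knockout, 28.97% of the wild-type CPM per library total. Wild-type cells or RNA mixed into the knockout samples would leave at least that share of each wild-type transcript, yet 175 of 1109 genes above 100 CPM in wild type lay under 14.5% of their wild-type level in both knockout libraries, with tdcB at 0.0889%, ansB at 0.239%, tnaA at 0.608% and aspA at 0.924%. Such mixing is thus excluded as the source of most of the cyaA counts. Reads from parts of the locus outside the deletion may account for them, but with one count per gene this cannot be told apart from transcripts that cross the locus.

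The second pattern is the fall of anaerobic genes beside the rise of iron and acid genes. Wild-type cultures sampled at a later growth stage would lower the stationary-phase genes in the knockout, where 14 were higher and 6 lower. The call for that list was lost with an estimated correlation (camera adjusted p = 0.516) and with total-count scaling (camera adjusted p = 0.055). The knockout may itself have moved the stationary-phase genes, so they cannot decide on the growth stage of the wild-type cultures. Knockout cultures sampled at a later stage would lower ribosomal protein genes, of which 48 were higher and 3 lower. With an estimated correlation the call for the ribosomal protein list was lost (camera adjusted p = 0.613). These genes too may have been moved by the knockout itself, so they cannot decide on the growth stage of its cultures. The 14 higher stationary-phase genes go with a later stage of the knockout cultures, and the 6 lower ones do not. The higher ribosomal protein genes, the higher fis (1.71) and the lower raiA (-5.36) go with a later stage of the wild-type cultures. Less oxygen in the wild-type cultures would have repressed sdhCDAB and cyoABCDE there, yet these 9 genes were all lower in the knockout (median log2 fold change -2.013), cyoA alone turning upward with total-count scaling (0.22). In contrast fnrS, the RNA made without oxygen, was lower in the knockout (-5.98), which goes with less oxygen in wild type. The knockout may itself have moved these genes, so they cannot decide on oxygen. A later stage of the knockout cultures stays open, since the ribosomal protein genes and most of the stationary-phase genes called point opposite ways. A later stage of the wild-type cultures and less oxygen in them stay open, since their markers went both ways. The knockout of cyaA, the biological difference that the design names, may contribute and was not tested apart from the strain, with cAMP itself not analysed here.

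The third pattern is the lower rRNA genes, 12 of 22 past the threshold with TMM scaling, made up of 7 for 16S and 5 for 5S rRNA and none for 23S. With total-count scaling, which moved log2 fold changes up by a median of 0.49, only 1 was still lower, while 11 were with upper-quartile scaling and 11 with the size factors of DESeq2, so the scaling of the libraries stays open for the calls, but it cannot move 16S and 23S counts apart. Lower transcription of the rRNA operons, which hold both, would leave the ratio of 23S to 16S counts unchanged if depletion treated both alike. The mean ratio was 1.409 times as high in the knockout as in wild type. How depletion acted on each species is not known, so the ratio cannot decide on lower transcription as the whole cause. Of the 10 tRNA genes between the 16S and 23S genes 1 was higher and 2 were lower, against 46 and 8 of the 73 others (medians -0.05 and 0.66). The others include tRNA genes that lie past the 23S gene of an rRNA operon, so this does not set operon genes against the rest. A permutation test of the means (p = 0.069) was set aside because near-identical copies are not independent. Lower transcription of the rRNA operons therefore stays open. The share of rRNA counts differed by 0.8997 percentage points between the 2 wild-type libraries and by 0.378 between the genotype means, and a difference in rRNA depletion cannot be told apart from one in the cells, since depletion was not measured apart from the counts.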
